A study of Homo sapiens with 4 samples.

How the data were processed

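Total RNA of H9 human embryonic stem cells was isolated with a column kit, converted to biotin-labelled cRNA and hybridised to Illumina expression arrays, per the labels' protocols. There were 4 samples, 1 in each group of high or low density, with or without 20 mM added bicarbonate, all collected on day 2. The groups were taken from the sample titles, and the meaning of the densities from the growth protocol in the labels. Nothing in the labels gives a batch, slide or scan.

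The deposited table of unnormalized values holds 1 probe intensity per array, and its deposited detection p-value estimates the share of negative-control probes that were brighter. The steps of that p-value are 0.0013 wide, which fits 770 negative controls. The authors also deposited log2 values for the same arrays, with a median of 6.02 on each array and nearly identical quantiles. Their scale was taken from the values, and the background and normalization steps behind them are not given in the sources used here. Each array's log2 values had a Spearman correlation of 1.00 with its own intensities and of at most 0.95 with those of another array. Each detection column followed the intensities to its left with a Spearman correlation of -0.99. The scanner software and its background setting are not given in the sources used here.

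Intensities were corrected and normalized with neqc of limma 3.58.1 in R 4.3.3, which fits a normal-exponential background from the level of the negative controls, here inferred from the detection p-values, adds an offset of 16 and sets the quantiles of the 4 arrays equal. The background fit pulls weak signals less toward each other than uncorrected values do, so fold sizes and counts depend on it. All further steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Quantile normalization removes any change common to all genes, so differences are relative to the typical gene of an array.

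Probes were named from the platform annotation, in which 30098 of 47293 probes had 1 gene symbol, 8 had several and 17187 had none and were left unnamed. Of the probes with 1 symbol, 30059 matched a current gene table by gene ID, and 0 symbols changed. A gene was represented by its probe with the highest mean log2 intensity among those detected (p-value under 0.01) on at least 1 array, which gave 10457 genes. A gene was counted as measured in a comparison when that probe was detected on every array compared. A gene with no detected probe on 1 of 2 arrays got a lower bound for its fold, from the brighter array's normalized value against the higher of the dim probe's own value and the lowest value of any detected probe on the dim array. Unnamed probes entered the normalization and no count of genes.

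The comparisons were high against low density in control medium, bicarbonate against control at high and at low density, high against low density with bicarbonate, and the difference between both bicarbonate differences. With 1 array per group no test was run. Genes at least 2-fold apart were counted. The following choices were made before the data were examined: the groups, the comparisons, the alternatives unless stated, 30 gene lists from textbook knowledge and the rule for named genes. That rule takes, for every comparison but that of density with bicarbonate, the 10 highest and 10 lowest genes among those measured and at least 2-fold apart. For the first 3 it adds the 3 largest fold bounds per direction, and it takes from each list the 4 measured members with the largest absolute difference. Genes without an established name, pseudogenes and sex-specific genes are not named.

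For each list the text gives the members at least 1.5-fold higher or lower, the median log2 difference, and its percentile among 10000 random lists of the same size drawn from the same 20 bins of mean intensity. Percentiles below 2.5 or above 97.5 are called outside the central 95%, and lists with fewer than 3 measured genes got none. These describe the arrays and are not tests. Some lists share members, so their results are not independent of each other. The slope between both density differences was an orthogonal regression through 0, with intervals from 500 resamplings of genes. The agreement of probes was computed on the 2 brightest probes of genes with at least 2 probes detected on all 4 arrays, with intervals from 2000 resamplings of genes.

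The procedure was tested on simulated data for high against low density in control medium, but run on the 8554 genes detected on all 4 arrays and not on the 8936 measured in that comparison, with 200 genes given a known change. Planted log2 differences of 1, -1, 2 and -2 came back with medians of 0.99, -0.92, 1.96 and -1.88, and 0% of the unchanged genes were 2-fold apart. The simulation has only technical noise of a chosen size, which was not set from the disagreement between probes. Between probes of a gene, the real log2 differences of this comparison had a standard deviation of 0.355. The 0% is thus no error rate for the counts below. A planted slope of 1 came back as 0.99, and as 0.94 by least squares on genes chosen by the difference in control medium. For the difference between both density differences, 4% of 100 random lists lay outside the central 95%. As both sides were random lists, this checks the ranking only and not lists of genes that vary together.

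The alternatives were no background correction, an offset of 50, equal medians without quantile normalization, the authors' deposited log2 values, a detection p-value under 0.05, a log2 intensity of at least 8, the mean of all detected probes of a gene, each other probe of a named gene, and random lists from all measured genes. Leaving the low-density bicarbonate array out of the normalization was added after the data were seen.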

Results

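Gene expression was measured in H9 cells, an established human embryonic stem cell line, after 2 days in culture on a basement membrane matrix in E8, a defined serum-free medium. The cells were grown at high density (above 90% confluence) or low density (below 70% confluence), each in unmodified E8 (control) or in E8 with 20 mM sodium bicarbonate added. The title of the series frames the question as what limiting the acidification of the medium does for pluripotent cells at high density. Each of the 4 combinations was measured on 1 Illumina expression array, so no difference below has a replicate check and no p-value is given. The number of arrays limits the precision, and the only spread at hand was the disagreement between different probes of the same gene. Such probes read the same RNA on the same array. Their disagreement therefore holds no variation between cultures, RNA samples or arrays and is not the error of a group difference. Of 47293 probes, 14710 were detected in the high-density control, 15213 at high density with bicarbonate, 14878 in the low-density control and 14128 at low density with bicarbonate. The median intensity before normalization was 162.7, 117.4, 166.6 and 153.5 on these arrays, lowest at high density with bicarbonate. All differences are of normalized log2 intensity on the brightest detected probe of a gene. No genomic positions are given, because no genome was used here.

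The first comparison asked how cells at high density differed from cells at low density in control medium. Among genes detected on both arrays, the gene that stood highest at high density was CDKN1A, the cyclin-dependent kinase inhibitor p21 and a target of p53, at 19.4-fold (log2 difference 4.28). It was followed by TXNIP, an inhibitor of thioredoxin that limits glucose uptake, at 11.02-fold (3.46), and by the metallothioneins MT1E at 8.66-fold (3.11) and MT1G at 6.05-fold (2.60). Next came RDM1 (2.75), TMEM64 (2.51), OVGP1 (2.45), SYT7 (2.34), the AP-1 subunit JUN (2.33) and KLHL24 (2.29). GDF15, a secreted stress cytokine, was detected at high density and not well above background at low density, which makes it at least 29.8-fold higher. The growth factor PDGFB was likewise at least 8.73-fold higher and the metallothionein MT2A at least 7.22-fold higher. Of the genes detected on both arrays, those that stood lowest were the translation initiation factor EIF5 (-2.47), PKDCC (-2.07), the ribosome biogenesis factor UTP14A (-2.06), the hyaluronan synthase HAS3 (-2.03), PAFAH1B1 (-2.02), CCKBR (-1.99), UHRF1 of DNA methylation maintenance (-1.97), TP53I3 (-1.95), the RNA exosome subunit EXOSC4 (-1.91) and PCF11 (-1.90). The endoderm factor FOXA2 was at least 7-fold lower, NCOA5 at least 5.84-fold and CYREN at least 5.09-fold. Second probes gave log2 differences of -0.50 for EIF5, -0.27 for TP53I3 and 0.40 for SYT7, far smaller than those of the brightest probes, while second probes of UTP14A (-1.83), PKDCC (-1.60) and TMEM64 (1.81) lay close to them. In all, 337 of 8936 measured genes were at least 2-fold higher at high density and 254 were at least 2-fold lower. A further 54 genes were higher and 44 lower by a fold bound of at least 2.

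Among gene lists fixed in advance with at least 3 measured genes, those of metallothioneins and p53 targets stood farthest above 0 at high density in control medium. The MondoA and thioredoxin-interacting family had 2 measured genes, TXNIP and ARRDC2 (-0.47), with a median of 1.496 and no percentile. Of 16 measured p53 targets, 12 were at least 1.5-fold higher and 1 was lower, with a median log2 difference of 1.02 at percentile 100 of 10000 random lists matched on intensity. PHLDA3 (2.05) and DDB2 (1.85) followed CDKN1A, and TP53I3 was the member that was lower. All 4 measured metallothioneins were higher, with a median of 2.16 at percentile 100. Of 9 measured genes of the FOXO and insulin withdrawal list 5 were higher, with a median of 0.97 at percentile 99.98. They included KLHL24 and the insulin receptor substrates IRS2 (1.16) and IRS1 (1.01). Of 17 hypoxia targets 7 were higher and 0 lower, with a median of 0.56 at percentile 100, led by FAM162A (1.71), the mTORC1 inhibitor DDIT4 (1.69) and the mitophagy receptor BNIP3 (1.43). Of 16 FGF and ERK targets 6 were higher, with a median of 0.50 at percentile 99.98, led by the immediate early gene EGR1 (2.28) and by ETV5 (1.01). In the list of ATF4 targets of the amino acid response, 8 of 27 were higher and 2 lower, with a median of 0.38 at percentile 99.99. VLDLR (1.84) and ATF3 (1.53) were among the former. Genes of G2 and mitosis had a median of 0.39 at percentile 99.99, with 10 of 27 higher, among them NEK2 (1.27) and PLK1 (0.98). Of 21 lysosome and autophagy genes 7 were higher and 2 lower, with a median of 0.39 at percentile 99.9. Its most different member was LAMP2 (1.43), whose other 4 probes stood at 0.53, 0.37, -0.32 and -0.37, and GABARAPL1 stood at 1.39.

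Other lists were lower at high density in control medium, while those of G2 and mitosis and of FGF and ERK targets were higher, as given above. Of 25 measured genes of ribosome biogenesis and MYC targets, 14 were at least 1.5-fold lower and 0 higher, with a median of -0.62 at percentile 0.0. RRP9 (-1.29), RRS1 (-1.15) and NOP56 (-1.15) were among them. Of 25 genes of S phase and replication 9 were lower and 0 higher, with a median of -0.42 at percentile 0.0, including the replication factor GINS3 (-1.56), the helicase subunit MCM5 (-1.26) and cyclin E1, CCNE1 (-1.08). Cholesterol and fatty acid synthesis had a median of -0.43 at percentile 0.0, with 8 of 26 genes lower, including the desaturase FADS2 (-1.68) and lanosterol synthase, LSS (-1.24). In the list of endoplasmic reticulum chaperones the median was -0.37 at percentile 0.87, although only 2 of 14 genes were lower by 1.5-fold and 2 were higher. Of 4 measured NODAL and activin targets 3 were lower, with a median of -0.77 at percentile 0.28, namely SMAD7 (-1.49), LEFTY2 (-0.90) and CRIPTO (-0.64).

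The pluripotency list had a median of -0.21 at percentile 0.5, with 7 of 26 measured genes at least 1.5-fold lower and 1 higher. OTX2 was lower (-1.12) and UTF1 higher (1.18). The core factors POU5F1 (-0.35), NANOG (-0.40) and SOX2 (0.09) all differed by less than 1.5-fold. These 3 genes were chosen after their values were seen. Of the lists for other cell types, that of fibroblasts had a median of 0.45 at percentile 99.4, with 4 of 11 genes higher, among them the actin ACTA2 (1.65) and TAGLN (0.91). Neuroectoderm genes had a median of -0.06 at percentile 36.8. Too few members were measured for a percentile in the lists of primitive streak and mesoderm (2 genes), definitive endoderm (1), trophoblast and amnion (1), and blood and endothelium (0).

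The second probes of 1738 genes gave a Pearson correlation of 0.56 across genes with the brightest probes (95% interval over genes 0.52 to 0.60), and genes are not independent replicates. With the alternative settings, the 591 genes at least 2-fold apart in this comparison became between 194 (no background correction) and 782 (detection p under 0.05). Of the 15 lists outside the central 95% of random lists, 10 stayed there under every alternative that left them at least 3 measured genes. Those of pluripotency, fibroblasts, FOXO, ATF4 targets and endoplasmic reticulum chaperones did not. The FOXO median fell to 0.381 with a log2 intensity of at least 8. That of ATF4 targets fell to 0.101 with the mean of all detected probes.

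**Figure D1:**
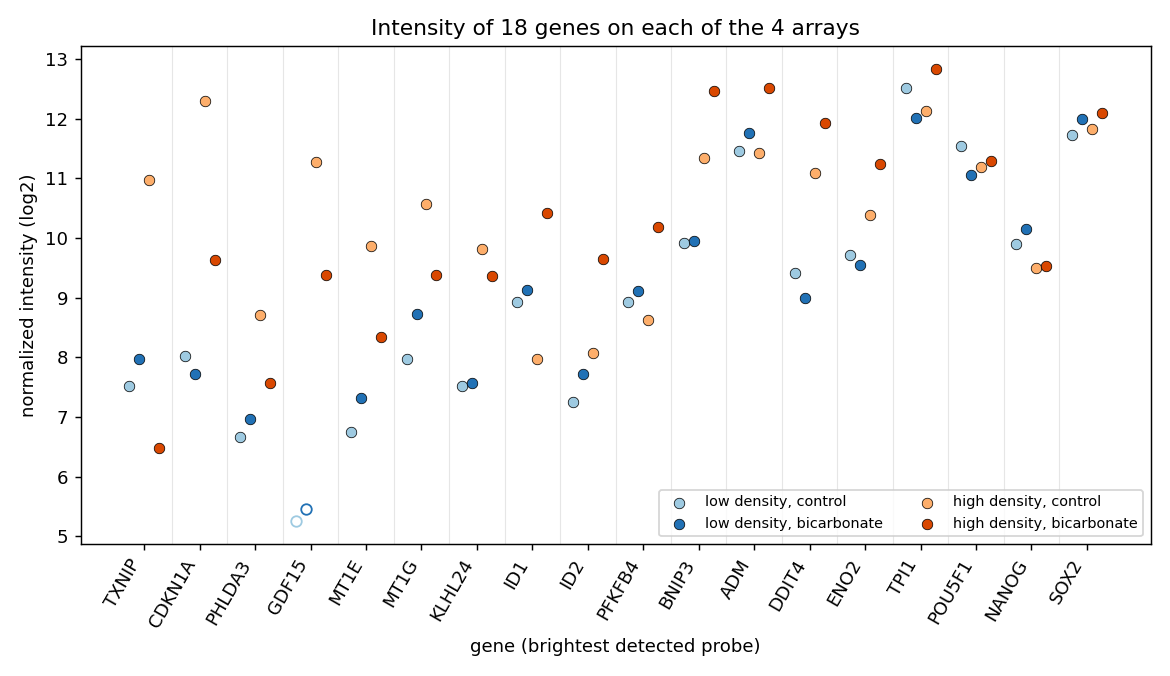
Normalized log2 intensity of 18 genes on each of the 4 arrays, 1 point per array on the brightest detected probe; open points mark an array on which the gene was not detected. The point for TXNIP at high density with bicarbonate lies lowest of its 4, while ENO2, BNIP3 and DDIT4 lie highest on that array.

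The second comparison asked what added bicarbonate did at high density. With bicarbonate TXNIP was 22.5-fold lower than in the high-density control (-4.49) and CDKN1A was 6.36-fold lower (-2.67). GDF15 was 3.73-fold lower (-1.90), and the actins ACTG2 (-1.81) and ACTA1 (-1.68) and the metallothioneins MT1E (-1.53) and MT1H (-1.50) were also among the lowest. Members of the actin and metallothionein families are so similar that a probe of 1 member can bind others. The remaining lowest genes code for small noncoding RNAs, namely SNORD3D (-1.62), RPPH1 of RNase P (-1.47) and RN7SK (-1.46, with -2.22 on its second probe). Measured small nucleolar RNAs, a class chosen after these values were seen, had a median of -0.49, with 14 of 36 at least 1.5-fold lower. Small nuclear RNAs, chosen likewise, had a median of -0.26, with 2 of 9 lower. The highest genes were ID1, an inhibitor of differentiation induced by BMP signals, at 5.44-fold (2.44), the neuronal pentraxin NPTX1 (1.83), ZNF239 (1.67), ID2 (1.57, and 1.73 on its second probe), PFKFB4, a regulator of glycolysis (1.56), FAM124A (1.45), the stress transcription factor DDIT3 (1.43), PCF11 (1.39), GALNT18 (1.38) and PPP1R10 (1.36). Not well above background in 1 of the arrays were RNY4, ZFP36L2 and SLC38A7, at least 3.96-fold, 3.50-fold and 2.496-fold higher, and SNORD80, NHLH2 and SNORD83B, at least 3.08-fold, 2.51-fold and 2.42-fold lower. In all, 48 of 9188 measured genes were at least 2-fold higher and 55 lower, but 22 and 17 when genes needed a log2 intensity of at least 8.

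Glycolysis and hypoxia genes were higher with bicarbonate at high density. The median of 21 glycolysis genes was 0.39 at percentile 100, with 5 at least 1.5-fold higher and 0 lower. PFKFB4, the enolase ENO2 (0.86), TPI1 (0.72) and the aldolase ALDOA (0.71) differed most. Of 20 hypoxia targets 7 were higher and 0 lower, with a median of 0.55 at percentile 100. BNIP3 (1.12), the peptide hormone ADM (1.09) and DDIT4 (0.84) led that list beside PFKFB4. Both lists hold PFKFB4, SLC2A1, HK2 and PDK1, so their medians are not independent. Of 6 BMP targets 3 were higher and 1 lower, with a median of 0.53 at percentile 99.95, namely ID1, ID2 and ID3 (0.90) against the inhibitory SMAD6 (-0.67). Neuroectoderm genes had a median of 0.41 at percentile 99.8, with 3 of 8 higher, such as SOX21 (1.22) and POU3F1 (0.99), and 1 lower, SOX3 (-0.72). The pluripotency list had a median of 0.16 at percentile 99.7, with 3 of 26 genes higher, the methyltransferase DNMT3B (0.62), VRTN (0.62) and OTX2 (0.61). POU5F1 (0.09), NANOG (0.04) and SOX2 (0.27) differed by less than 1.5-fold.

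Lists of p53 targets, metallothioneins, FOXO genes and heat shock genes were lower with bicarbonate at high density, while other stress lists were inside the random range. The latter were ATF4 targets (0.03, percentile 63.4), with DDIT3 and CHAC1 (1.18) higher, NRF2 targets of the oxidative stress response (-0.07, percentile 19.0) and endoplasmic reticulum chaperones (-0.04, percentile 24.7). Of 19 p53 targets 9 were at least 1.5-fold lower and 0 higher, with a median of -0.57 at percentile 0.0. PHLDA3 (-1.14) and SESN1 (-0.87) followed CDKN1A and GDF15. Of 6 metallothioneins 5 were lower, with a median of -1.01 at percentile 0.0. Of 13 FOXO and insulin withdrawal genes 4 were lower and 1 higher, with a median of -0.41 at percentile 0.01. Heat shock genes had a median of -0.33 at percentile 0.0, with 3 of 13 lower, including the near-identical HSPA1B (-0.98) and HSPA1A (-0.71). Smaller shifts were seen for oxidative phosphorylation, with a median of -0.15 at percentile 0.08 and 2 of 42 genes lower, and for G2 and mitosis, with a median of -0.13 at percentile 1.46 and 2 of 27 lower, among them BIRC5 (-0.95). Lists of ribosome biogenesis (0.10, percentile 91.0), S phase (0.03, percentile 65.5), cholesterol and fatty acid synthesis (0.04, percentile 73.9) and acid-base and lactate transport (0.14, percentile 96.8) had medians inside the central 95% of random lists. In the last of these, the membrane carbonic anhydrase CA4 was higher (1.10) and the bicarbonate transporter SLC4A7 lower (-0.70).

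The high-density control array enters both comparisons above, so an error on that array would move a gene in opposite directions in them, and no overlap between them is given. The correlation between the probes of 1738 genes was 0.46 (95% interval over genes 0.42 to 0.50). The 103 genes at least 2-fold apart became between 28 (no background correction) and 158 (detection p under 0.05). Of the 11 lists outside the central 95%, 6 stayed there under every alternative that left them at least 3 measured genes. Those of pluripotency, neuroectoderm, BMP targets, FOXO, and G2 and mitosis did not. With a detection p under 0.05 the median of BMP targets fell to 0.156 and that of neuroectoderm genes to 0.138.

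**Figure D2:**
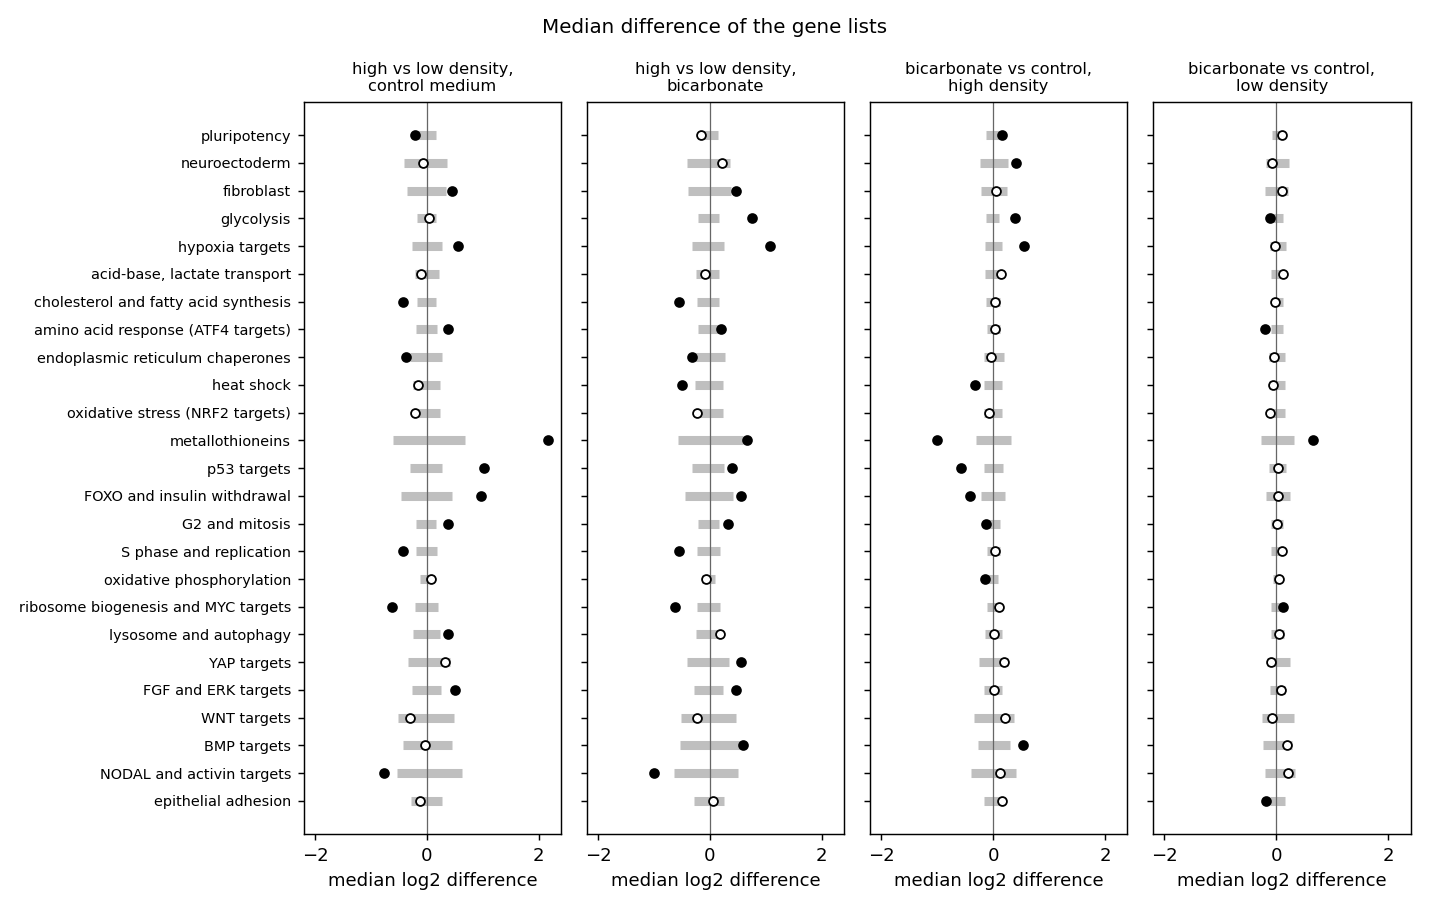
Median log2 difference of 25 gene lists (points) in 4 comparisons, with the central 95% of 10000 random lists matched on intensity (grey bars); filled points lie outside that range. Metallothioneins and p53 targets lie right of the bars for density in control medium (2.16 and 1.02) and left of them for bicarbonate at high density (-1.01 and -0.57), while glycolysis lies at 0.04 and 0.39.

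The third comparison asked what added bicarbonate did at low density. Only 8 of 8973 measured genes were at least 2-fold higher and 9 were at least 2-fold lower. The highest were DNTTIP2 (1.29), the histone genes H2BC12 (1.21), H2BC5 (1.18) and H2AC18 (1.04), NETO2 (1.10), the amino acid transporter SLC38A4 (1.04), AKAP12 (1.04, but 0.15 on its second probe) and the actin capping subunit CAPZA1 (1.01). The lowest were the spliceosomal RNA RNU4-1 (-1.27), the deubiquitinase USP22 (-1.21), the collagen chaperone FKBP10 (-1.18), the import receptor IPO7 (-1.15), the acetyltransferase EP300 (-1.03), TRA2A (-1.02), ZNF121 (-1.02) and OPN3 (-1.01). SNRPE was at least 2.08-fold higher, and RNA28SN5, NPTX1 and ATRX at least 2.93-fold, 2.20-fold and 2.15-fold lower. CDKN1A (-0.29), TXNIP (0.45), ID1 (0.20) and BNIP3 (0.02), which were far apart at high density, differed by less than 1.5-fold. CDKN1A, ID1 and BNIP3 were named here after their values were seen.

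Of the lists, metallothioneins were higher with bicarbonate at low density, with a median of 0.66 at percentile 100 and 2 of 4 genes at least 1.5-fold higher, MT1F (0.85) and MT1G (0.75). The 3 measured endoderm genes had a median of 0.66 at percentile 99.9, with FOXA2 (0.93) and AFP (0.66) higher. Of the ATF4 targets 2 of 26 were lower and 1 higher, with a median of -0.21 at percentile 0.0. The tRNA exporter XPOT (-0.999) and VLDLR (-0.66) were lower. Epithelial adhesion genes had a median of -0.19 at percentile 0.14, with 2 of 17 lower, ESRP1 (-0.68) and DSP (-0.70), although another probe of DSP stood at 0.14. Glycolysis had a median of -0.10 at percentile 1.59, with 1 of 21 genes lower, PGAM1 (-0.65), and this median was 0.01 when arrays were set to equal medians. Ribosome biogenesis had a median of 0.12 at percentile 97.52, with 0 of 26 genes past 1.5-fold. The p53 targets had a median of 0.03 at percentile 56.2, and pluripotency genes 0.11 at percentile 94.2, with CRIPTO (0.83) and OTX2 (0.66) higher and POU5F1 at -0.50, NANOG at 0.26 and SOX2 at 0.27.

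The probes of a gene tracked each other weakly in this comparison, with a correlation of 0.13 across 1738 genes (95% interval over genes 0.08 to 0.18). The 17 genes at least 2-fold apart became 1 without background correction and 44 with a detection p under 0.05, with equal medians 7 were higher and 13 lower, and the medians of endoderm, glycolysis and ribosome biogenesis moved inside the random range under at least 1 alternative.

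**Figure D3:**
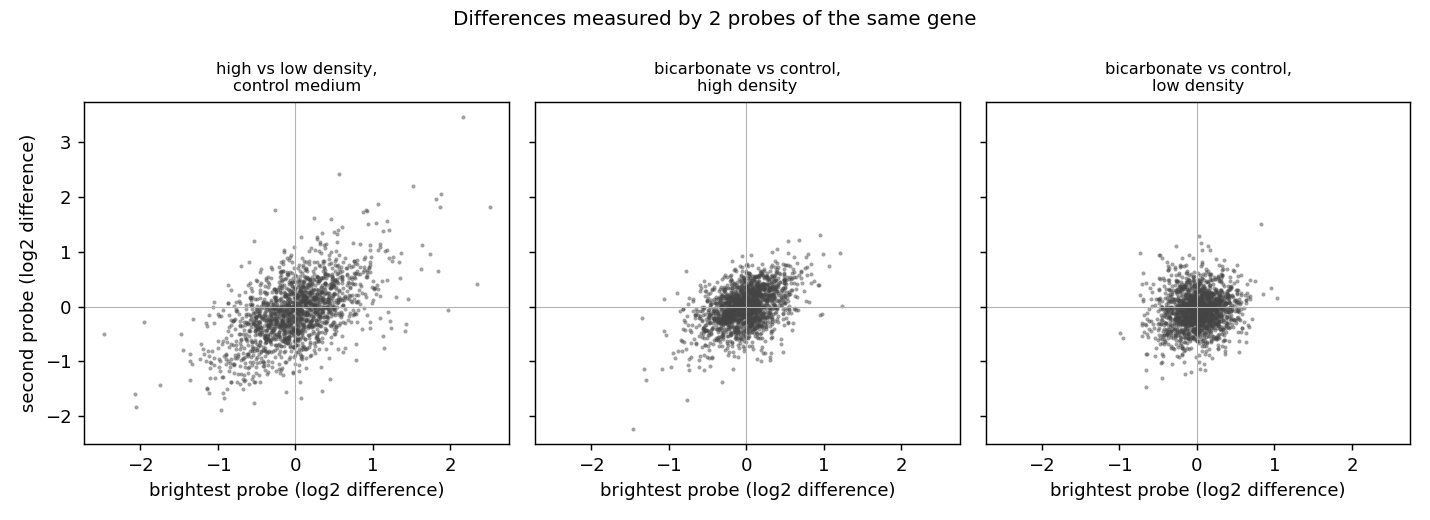
Log2 difference on the second brightest probe (y axis) against that on the brightest probe (x axis) of the same gene in 3 comparisons, 1 point per gene for genes with at least 2 probes detected on all arrays. The points follow the diagonal for density in control medium (r = 0.56) and bicarbonate at high density (r = 0.46), and form a round cloud for bicarbonate at low density (r = 0.13).

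The fourth comparison asked how high and low density differed when both media held added bicarbonate. CDKN1A was still 3.75-fold higher at high density (1.91), KLHL24 stood at 1.80, JUN at 2.26 and MT1E at 1.02. TXNIP was lower at high density (-1.48), opposite to its difference in control medium, and PCF11 stood at -0.29. Except for CDKN1A, TXNIP, KLHL24 and MT1E, which their lists name, these genes were picked after their values were seen. In all, 303 of 8836 measured genes were at least 2-fold higher and 259 lower, and 65 and 59 more by a fold bound of at least 2. With equal medians 292 were higher and 302 lower, so the majority turned. Of 21 glycolysis genes 14 were at least 1.5-fold higher and 0 lower, with a median of 0.76 at percentile 100, led by ENO2 (1.68) and the pyruvate kinase PKM (1.12). Of 15 hypoxia targets 12 were higher and 0 lower, with a median of 1.07 at percentile 100, led by DDIT4 (2.94) and BNIP3 (2.52). The high-density bicarbonate array, which had the lowest median intensity, also enters the second and the last comparison. The high glycolysis and hypoxia medians in those comparisons are therefore not independent of the ones here. The YAP targets had a median of 0.56 at percentile 99.8, against 0.33 at percentile 94.2 in control medium, with NUAK2 (2.403) and CCN1 (1.44) higher. Small signalling lists also lay outside the random range, with 5 measured BMP targets at 0.59 (percentile 98.5, ID2 at 1.93) and 4 NODAL and activin targets at -0.99 (percentile 0.1, CRIPTO at -1.22).

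Several lists stood on the same side of 0 with bicarbonate as in control medium. Ribosome biogenesis had a median of -0.63 at percentile 0.0, with NOP16 (-1.59) and RRS1 (-1.48) lower. S phase stood at -0.56 (percentile 0.0), cholesterol and fatty acid synthesis at -0.55 (percentile 0.0), G2 and mitosis at 0.32 (percentile 99.98), FGF and ERK targets at 0.46 (percentile 100), fibroblast genes at 0.46 (percentile 99.2) and endoplasmic reticulum chaperones at -0.32 (percentile 2.15). The p53 targets had a median of 0.39 at percentile 99.7, with 6 of 15 higher and 1 lower, where TP53I3 at -1.93 stood at 0.20 on another probe. Metallothioneins had a median of 0.66 at percentile 98.3, FOXO genes 0.56 at percentile 99.3 and ATF4 targets 0.21 at percentile 98.8, where VLDLR (3.04) and CHAC1 (2.58) were higher. Heat shock genes had a median of -0.51 at percentile 0.01, with 6 of 13 lower. The pluripotency list had a median of -0.17 at percentile 7.02, with OTX2 (-1.16) lower, NANOG at -0.62, POU5F1 at 0.24 and SOX2 at 0.10.

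The density differences in control medium and with bicarbonate share no array, so they could be set against each other. The orthogonal regression slope of the difference with bicarbonate on that in control medium was computed over 889 genes at least 2-fold apart in either. It was 0.98 (95% interval over genes 0.93 to 1.04). This slope nears 1 for any positively related differences of like spread. Over the measured genes, the standard deviations were 0.538 in control medium and 0.53 with bicarbonate. The slope therefore does not tell how much of each gene's difference was kept. Among 8554 genes detected on all 4 arrays, the correlation across genes was 0.58. Of these, 199 were at least 2-fold apart in the same direction in both media, where 17.5 would be shared by independent lists, and 2 in opposite directions. Chosen by the difference in control medium, 550 genes had a median ratio of 0.63 between the difference with bicarbonate and that in control medium, and 540 genes chosen by the difference with bicarbonate had 0.62 for the inverse ratio. The shortfall was thus alike whichever difference chose the genes. Least squares slopes through 0 were 0.624 for the former genes and, with the differences exchanged, 0.626 for the latter. The simulated data, with a planted slope of 1, gave 0.94 for genes chosen by control medium. At the simulated noise, selection thus left a smaller shortfall, and larger noise was not simulated. The 562 genes at least 2-fold apart with bicarbonate became between 205 (no background correction) and 813 (detection p under 0.05). Of the 17 lists outside the random range with bicarbonate, 12 stayed there under every alternative that left them at least 3 measured genes. Those of BMP targets, ATF4 targets, metallothioneins, p53 targets and FOXO did not.

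The last comparison asked whether the bicarbonate difference depended on density, as the difference at high density minus that at low density on a log2 scale. TXNIP stood farthest from 0 at -4.95, followed on the low side by CDKN1A (-2.38), ACTA1 (-2.32), RPPH1 (-2.26), MT1E (-2.10), H2BC12 (-2.03), MT1G (-1.94), ACTG2 (-1.90), CCAR1 (-1.86) and GLIPR1L1 (-1.78). On the high side stood ID1 (2.24), FKBP10 (2.21), GALNT18 (1.90), USP22 (1.72), the glutathione-degrading CHAC1 (1.71), EP300 (1.70), PCF11 (1.61), SYT6 (1.61), KMT2E (1.60) and FAM124A (1.58). The median for glycolysis was 0.45 at percentile 100, with 8 of 21 genes at least 1.5-fold above 0 and 0 below, led by PFKFB4 (1.37) and TPI1 (1.21). Hypoxia targets stood at 0.57 (percentile 100), BMP targets at 1.10 (percentile 100), neuroectoderm genes at 0.64 (percentile 99.95) and epithelial adhesion at 0.34 (percentile 99.7, ESRP1 at 1.04). ATF4 targets stood at 0.28 (percentile 99.8). Metallothioneins stood at -1.77 (percentile 0.0), p53 targets at -0.71 (percentile 0.0, PHLDA3 at -1.44), heat shock genes at -0.45 (percentile 0.01) and FOXO genes at -0.49 (percentile 0.71). The pluripotency list (-0.04, percentile 39.1) and YAP targets (0.17, percentile 85.7) lay inside the random range.

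In all, 165 of 8554 genes lay at least 2-fold above 0 in the difference of differences and 208 below, but 74 and 73 when genes needed a log2 intensity of at least 8. An additive fit would take this difference as its error and was not run. Across these genes, the difference of differences divided by 2 had a standard deviation of 0.243. The mean bicarbonate difference had a smaller one (0.193), and the mean density difference a larger one (0.473). That 0.243 exceeds 0.193 restates the negative correlation of both bicarbonate differences (-0.235), which is taken up below. It is no separate sign of a response that depends on density. The correlation between probes was 0.24 (95% interval over genes 0.19 to 0.28). Of 71 genes at least 2-fold from 0 on the brightest probe, 55 had the same sign on the second probe but only 12 were 2-fold there too, with a median ratio of 0.28, against 77 and 31 of 87 and a ratio of 0.66 for density in control medium. The 373 genes became between 97 (no background correction) and 580 (detection p under 0.05), while ATF4 targets, p53 targets and FOXO genes moved inside the random range when genes needed a log2 intensity of at least 8, and ATF4 targets (0.17) also with the mean of all detected probes.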

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

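The tests of quantile normalization, of the 1.5-fold differences at low density and of second probes for glycolysis genes, and the count of signs over all genes, were chosen after related values had been seen.

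For 14 named genes the bicarbonate difference was at least 1.5-fold at both densities with opposite signs, and for 2 gene lists the medians had opposite signs and lay outside the central 95% of random lists at both. Of the 14 genes, 10 were named for their difference of differences, a rule that favours opposite signs. Among the 218 genes named otherwise 4 had opposite signs and 1 the same sign. Independent differences would give 4.2 and 3.9 there, so opposite signs were not in excess among those genes. Over all 8554 genes, 45 had opposite signs and 14 the same sign past 1.5-fold at both densities, where independent differences would give 12.9 and 13.0. These differences were not tested because each group has 1 array, and the excess of opposite signs goes with the negative correlation taken up next. Other genes and lists had opposite signs with a smaller difference at 1 density, such as TXNIP (-4.49 and 0.45). Metallothioneins had a median difference of differences of -1.77, with -1.01 at high density and 0.66 at low density. Of their 4 measured members, MT1G (-1.94) and MT1F (-1.61) were past 1.5-fold at both densities. MT1E (-2.10) and MT1X (-0.45) stood at only 0.56 and 0.12 at low density. As their probes can bind other members, members that go together are not separate support. Glycolysis genes had a median of 0.45, with 0.39 at high and -0.10 at low density. Their opposite sign was lost with equal medians (0.008 at low density), and their low-density median moved inside the random range with the mean of all detected probes. Below 0 in the difference of differences were also the actin ACTA1 (-2.32), the RNase P RNA RPPH1 (-2.26), the histone H2BC12 (-2.03), CCAR1 (-1.86), GLIPR1L1 (-1.78), CAPZA1 (-1.73) and the respiratory chain subunit UQCRH (-1.34). Above 0 were FKBP10 (2.21), EP300 (1.70), SYT6 (1.61), KMT2E (1.60) and EIF5 (1.54), where EIF5 stood at 0.06 on its second probe.

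Across 8554 genes the bicarbonate differences at high and low density were negatively correlated (r = -0.23), although they share no array. If genes responded in opposite ways, 1 probe of a gene at high density should go against another probe of that gene at low density. Over 1738 genes with at least 2 probes detected on all 4 arrays, the covariance between probes was -0.003 times that within a probe (95% interval over genes -0.14 to 0.11). For these 1738 genes as a set, this argues against a density-dependent response as the source of the correlation. It says nothing of genes without a second detected probe, nor of single genes such as TXNIP. Quantile normalization is argued against as well, since the correlation was -0.27 with equal medians. The correlation may instead come from a component of single probes that pairs the arrays, whose origin was not tested. The same ratio of -0.003 bears on both explanations and is not a separate test of this one.

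The differences with bicarbonate at low density were small, and the question is whether those of at least 1.5-fold belong to genes or to single probes. The threshold was first 2-fold, which left 1 gene with a second probe, and was then lowered, and the bound on the ratio of probes below was moved to 0 after the ratio had been seen. Among 55 genes past 1.5-fold on the brightest probe, the second probe had the same sign in 37, with a median ratio of 0.27 (95% interval over genes 0.14 to 0.43). Noise of single probes as the whole cause would leave a ratio of 0 and is argued against, but less was shared than at high density, where 94 of 111 genes kept the sign with a ratio of 0.56 (0.46 to 0.75). Whether the shared part is a response to bicarbonate or another difference between these cultures, their RNA or their arrays stays open with 1 array per group. A brightness trend common to the probes of a gene was not tested.

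Glycolysis genes were higher with bicarbonate at high density (median 0.39). A trend with probe brightness is argued against, as the list lay at percentile 100 of intensity-matched lists with quantile and with median scaling. Noise of single probes is too, as the second probes of 9 genes had a median of 0.54 (95% interval over genes 0.43 to 0.98) and 9 were above 0. Both checks use the same RNA on the same arrays, so they cannot bear on a difference in RNA, labelling or array. The high-density bicarbonate array had the lowest median intensity before normalization (117.4). A response of these genes to bicarbonate, or to a condition of the culture that went with it such as cell number or oxygen, may account for the pattern. With 1 array per group, a difference between these cultures, their RNA or their arrays stays open too.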

How the results depend on the processing

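No analysis paired by replicate was possible because each group has 1 array and the labels give no replicate numbers. The arrays can be paired by density or by medium. Such a fit would take the difference of differences as its error and was not run. Leaving the low-density bicarbonate array out of the normalization was added after the data were seen and gave 574 and 99 genes at least 2-fold apart for density in control medium and bicarbonate at high density, against 591 and 103. Counts are given in the order density in control medium, bicarbonate at high density, bicarbonate at low density, density with bicarbonate and difference of differences, with 591, 103, 17, 562 and 373 in the main setting. Without background correction they were 194, 28, 1, 205 and 97. With a log2 intensity of at least 8, which leaves fewer genes, they were 214, 39, 5, 227 and 147. An offset of 50 gave 62, 5 and 231 for the bicarbonate differences and the difference of differences. The authors' deposited log2 values gave 66 and 8 for bicarbonate at high and low density. A detection p under 0.05, which adds genes, gave 158, 44 and 580 for the bicarbonate differences and the difference of differences. Counts under the other settings stayed within 1.5 times, and the cause was not tested where none is named. At low density 47.1% of these genes were higher, against 35.0% (7 of 20) with equal medians, and for density with bicarbonate 53.9% against 49.2%. With a log2 intensity of at least 8, 56.4% against 46.6% were higher for bicarbonate at high density, and 50.3% against 44.2% for the difference of differences. With a log2 intensity of at least 8 the slope was 1.04, and 11 lists for density with bicarbonate and 5 for the difference of differences lay outside the central 95%, against 17 and 10. The median of glycolysis at low density was 0.008 with equal medians, against -0.10. Of 218 differences of at least 2-fold in named genes, 215 kept their sign under every setting that gave them a value. Most settings rescale the same probe on the same arrays and could hardly turn such a sign, so this count is a weak check. Other detected probes were compared for named differences of at least 1.5-fold. Of their values 44 lay within the standard deviation between probes, 45 moved farther with the same sign and 13 were reversed. Reversed signs came with other probes of a gene. For bicarbonate at low density CDKN1B stood at 0.12 (mean of probes) and 0.98 (other probe), and for the difference of differences at -0.52 and -1.93. Other probes of LAMP2 stood at -0.37 and -0.32 for density in control medium and at -0.34, -0.23 and -0.44 with bicarbonate. Another probe of DSP stood at 0.14 for bicarbonate at low density and -0.22 for density with bicarbonate, that of TP53I3 at 0.20 in the latter, and for the difference of differences those of MCM10 at 0.35, PHLDA1 at -0.016 and CLDN10 at 0.47. The cause was not tested. Signal near background limits all fold sizes of dim genes.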

Other observations

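Gene lists not yet described for some comparisons stood as follows. In control medium the glycolysis list lay inside the random range for density (median 0.04, percentile 64.5), with PGK1 (0.67) and ENO2 (0.66) higher and PFKFB3 lower (-0.81). Acid-base and lactate transport had a median of -0.11 at percentile 17.0, with the proton pump subunit ATP6V0A2 lower (-1.24) and the bicarbonate transporter SLC4A7 higher (1.11). Targets of NRF2, the regulator of the oxidative stress response, had a median of -0.21 at percentile 4.73, with thioredoxin reductase TXNRD1 lower (-1.14). WNT targets had a median of -0.31 at percentile 11.7, where ZNRF3 stood at -0.99. Epithelial adhesion had a median of -0.12 at percentile 18.6, with CLDN3 higher (1.63) and CLDN7 (-0.87) and CLDN6 (-0.83) lower. Oxidative phosphorylation stood at 0.08 (percentile 89.5), heat shock at -0.15 (percentile 9.03) and BMP targets at -0.04 (percentile 39.5), with SMAD6 (1.17) higher and ID1 (-0.95) lower.

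With bicarbonate at high density, the NRF2 target NQO1 was lower (-0.88), and WNT targets had a median of 0.22 at percentile 84.3, with the receptor FZD7 higher (0.94). YAP targets had a median of 0.20 at percentile 92.4, with AJUBA higher (1.03) and CCN2 lower (-0.96), and CCN2 stood at -1.10 on its second probe. Fibroblast genes had a median of 0.05 at percentile 57.3, where TAGLN (-1.29) was lower and the collagen COL1A1 (0.99) higher. Of the MondoA and thioredoxin-interacting family 3 genes were measured, with a median of -0.20 at percentile 18.8, and TXNIP at -4.49 stood apart from ARRDC2 (-0.20) and MLXIPL (0.81).

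Among 17187 probes without a symbol, 2662 were detected on both high-density arrays. Of these, 3 were at least 2-fold higher with bicarbonate and 25 lower. At low density 14 of 2580 were higher and 10 lower. Small nucleolar and small nuclear RNAs were grouped after some of them were seen among the lowest genes, so their medians are only descriptions. Small nucleolar RNAs had a median of 0.13 for density in control medium, 0.07 for bicarbonate at low density and -0.40 for density with bicarbonate. Small nuclear RNAs had medians of 0.12, -0.23 and -0.22 in these comparisons.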
